A study of Drosophila melanogaster with 10 samples.

How the data were processed

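Dscam transcripts were measured in 10 Drosophila libraries of 9 groups, embryo, L1 larva, L2 larva, L3 larva, pupa, adult brain, S2 cells (2 replicates) and 2 control mixtures. Per the labels' protocols, total RNA was reverse transcribed and amplified between constitutive exons 3 and 10 with indexed primers, the products were circularized, and a second PCR from exons 7 and 8 gave the shorter product that was sequenced, so that the variants of exons 4, 6 and 9 lie close together. The submitters' processing notes name Bowtie2 and the genome build dm3. The version of Bowtie2, the rule that assigns reads to variants, any filter and any use of molecular identifiers are not given in the sources used here. The deposited values are read counts per isoform, whole numbers with a different total in each library, and nothing in the files points to scaling. Each file lists all 19008 combinations of 12 exon 4, 48 exon 6 and 33 exon 9 variants. No coordinates are given, because the RefSeq table used for the gene name belongs to another build.

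Total counts ran from 5710130 to 15223401 over the 8 biological libraries. Shares in single libraries carry 95% binomial intervals, Clopper-Pearson for isoforms, pairs and control counts and Wilson for variants, and a count of 0 is given as an upper limit of 3 counts. PCR reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only.

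The computation used python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Counts were summed over isoforms for each of 93 variants. The comparisons of S2 cells, adult brain and whole animals were fitted together with edgeR's quasi-likelihood test on all 8 biological libraries in 3 classes, 5 whole animal stages, 1 brain library and 2 S2 libraries. The stages thus supply the spread, and the lone brain library is assumed to vary like the other classes. Library totals were the offsets, filterByExpr kept 92 variants, and p was adjusted by Benjamini-Hochberg over all of them at a threshold of 0.05. The fit had 5 residual degrees of freedom and a biological coefficient of variation of 27.5%. The trend over the 5 stages used the same test with stage order as a number, and its coefficient of variation was 32.2%. Fixed lists of variants were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 8 lists of a comparison. The lists are the proximal and distal parts of exons 4, 6 and 9, the blood cell exon 9 list (Ex9.6, Ex9.9, Ex9.13, Ex9.30 and Ex9.31) and the exon 4 developmental pair (Ex4.2 and Ex4.8), and Ex6.11 stood alone.

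On simulated counts with 20 of 93 variants changed, over 5 runs each, S2 cells against whole animals recovered 64% of changes of 1 and 100% of changes of 2 on the log2 scale. Brain against whole animals recovered 28% and 94%, brain against S2 cells 26% and 90%, and the trend 70% and 100%. In the trend these changes of 1 and 2 ran from embryo to the middle stage, and again from there to pupa. The trend's percentages thus stand for larger total changes than those of the other comparisons. False calls were 0.833%, 0.556%, 0.833% and 1.94% in that order. The simulation gave all variants and libraries of a comparison the same biological coefficient of variation. Its simulated shares did not have to sum to 1 within a cluster. The percentages hold for that setting and may differ for the real libraries.

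Isoforms were counted after thinning each library to 5710130 counts, as the mean of 100 seeded draws. The effective number is the exponential of Shannon entropy. Dependence of clusters is mutual information in bits minus its mean over 100 draws of independent choices at the same depth, tested on simulated mixtures. Background was taken from the control mixtures, whose inputs were defined as the 8 largest isoforms. Variants named are up to 12 with the largest positive and 12 with the largest negative log2 fold change among those past the threshold with at least 1% of their cluster in a library of the comparison. To these come the members of lists of 5 or fewer, the most used variant of each cluster, the 3 most abundant isoforms of each biological library, the 8 control inputs, and the 5 highest and 5 lowest pairs by observed over expected count in S2 cells.

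Tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were TMM factors, DESeq2 with its own size factors, limma on log2 of percent plus 0.01, no filter on low counts, each cluster fitted alone, thinned counts, 7 groups with the spread from the S2 pair, only the libraries compared, and leaving out each library in turn. For the lists they were camera with an estimated correlation and fry. Added after the data were seen were the control inputs as 8 isoforms that share no variant, the pairing within exon 9 variants used in S2 cells, and larvae against embryo and pupa, also with the exon 9 variants outside the blood cell list scaled to their own total. No library was left out of the main comparisons. Markers of other cell types could not be used, since 1 gene was measured.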

Results

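The transcripts of 1 Drosophila gene were profiled, Dscam (listed as Dscam1, locus tag Dmel_CG17800, in the RefSeq table used for names). Dscam encodes a cell surface receptor of the immunoglobulin superfamily that acts in neuronal self-recognition and is also expressed in blood cells. Exons 4, 6 and 9 each exist as a cluster of alternative variants, of which a transcript keeps 1 per cluster. The files list 12 exon 4, 48 exon 6 and 33 exon 9 variants, which makes 19008 combinations, called isoforms here, and give a read count for each. The variant Ex9.30 is the variant of exon 9 with that number, and Ex4.1-Ex6.3-Ex9.6 is the isoform made of the variants it names. There were 10 libraries. Whole animals were sampled as embryo, L1 larva, L2 larva, L3 larva and pupa, with 1 library each, and female adult brain gave 1 library. S2 cells, an embryo-derived line with properties of blood cells, gave 2 libraries. The other 2 libraries were control mixtures of 8 Dscam transcripts made in vitro. Total counts were 12889320 in embryo, 5710130 in L1 larva, 14351573 in L2 larva, 13566012 in L3 larva, 11904317 in pupa, 15223401 in adult brain, 12670675 and 6018591 in S2 cells, and 11052511 and 10504389 in control mixtures 1 and 2. No stage and no brain library had a replicate, so stages are compared as values, and the 5 stages serve together as the class of whole animals where a test was made. Shares of a cluster's counts in a single library had 95% Wilson intervals at most 0.0798 percentage points wide over the 744 shares of the 8 biological libraries. These intervals cover counting error only and understate the spread between libraries. Between the 2 S2 libraries the counts of 92 variants gave a chi-square of 163 per degree of freedom, far beyond counting error.

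The control mixtures show how often a combination that was not put in appears in mixtures where 1 isoform holds most counts. The 8 leading isoforms that share no variant with each other were the same in both mixtures, in opposite order of abundance, and the least abundant of them lay among recombinants by rank, at ranks 10 and 36 in mixture 1 and at ranks 12 and 21 in mixture 2. Ex4.10-Ex6.1-Ex9.26 made up 72.3% of the counts of mixture 1 and 0.00733% of those of mixture 2, and Ex4.6-Ex6.27-Ex9.13 made up 0.00312% and 74.9%. Between them lay Ex4.3-Ex6.41-Ex9.9, Ex4.7-Ex6.8-Ex9.10, Ex4.4-Ex6.10-Ex9.6, Ex4.11-Ex6.3-Ex9.30, Ex4.8-Ex6.17-Ex9.5 and Ex4.5-Ex6.42-Ex9.25, each 2.67- to 6.49-fold apart from the next in mixture 1 and 2.81- to 5.27-fold apart in mixture 2. Counts outside the 8 largest isoforms were 0.512% of mixture 1 (95% Clopper-Pearson interval 0.508% to 0.517%) and 0.732% of mixture 2 (0.727% to 0.737%). The 8 largest were not the 8 that share no variant, because recombinants of abundant inputs held ranks 7 and 8 in mixture 1 and ranks 6 and 8 in mixture 2. Counts outside the 8 isoforms that share no variant, a rule chosen after the values were seen, came to 0.655% and 0.935%. Of these, recombinants built only of input variants made up 0.380% and 0.546% of the libraries, and exon 9 came from another input in 76.3% and 82.3% of the recombinants. Exchange between copies of the same isoform cannot be seen, and 1 isoform held 72.3% and 74.9% of the mixtures. In libraries of many isoforms the share of recombinants may thus be higher. Isoforms holding a variant of no input made up 0.276% and 0.389%. The highest share of a variant of no input was 0.0225% for exon 4, 0.0140% for exon 6 and 0.0109% for exon 9, and these serve as the background of the biological libraries. The labels give neither the identity nor the concentration of the inputs, so recovery of a known ratio was not measured.

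**Figure D1:**
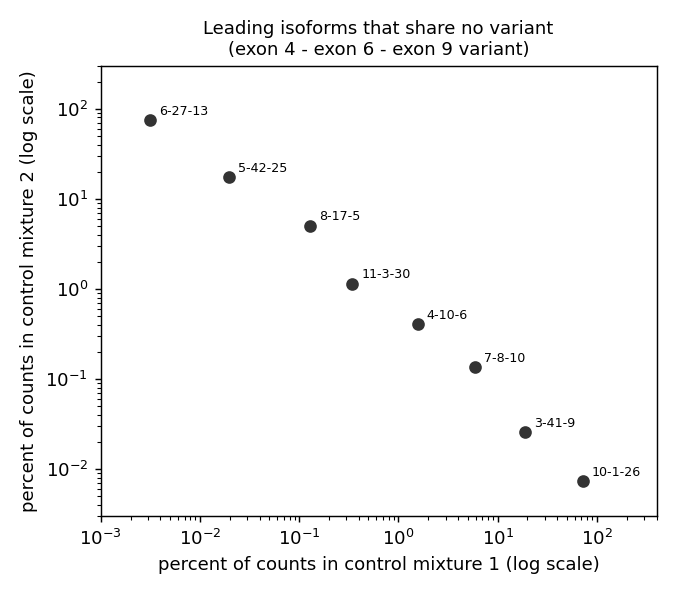
Percent of counts in control mixture 1 (horizontal, log scale) and control mixture 2 (vertical, log scale) of the 8 leading isoforms that share no variant, 1 point per isoform, named by its exon 4, exon 6 and exon 9 variant. Their order is opposite in the mixtures, from 72.3% and 0.00733% for Ex4.10-Ex6.1-Ex9.26 to 0.00312% and 74.9% for Ex4.6-Ex6.27-Ex9.13.

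S2 cells used far fewer Dscam isoforms than whole animals or brain. After thinning every library to 5710130 counts, 8099 and 7772 isoforms had a count in the S2 libraries, against 16559 ± 985 (SD, n = 5) in whole animals and 17482 in adult brain. S2 cells thus had 47.9% of the whole animal number. Control mixtures of 8 transcripts also had 4189 and 3902 isoforms with a count, so part of these numbers was background. Above the 99th percentile of the control isoforms outside the 8 largest, without thinning, lay 5055 and 5117 isoforms in S2 cells, 13994 ± 1893 in whole animals and 16236 in brain, or 36.3% for S2 cells against whole animals. The effective number of isoforms, the exponential of Shannon entropy, was 1305 and 1296 in S2 cells, 6862 ± 2403 in whole animals and 9258 in brain. L2 and L3 larva had the lowest values among animals, 4814 and 4765, and pupa the highest, 9910. The clusters did not share this evenly. Exon 9 had an effective number of 3.44 ± 0.0119 variants in S2 cells (n = 2), 17.9 ± 4.73 in whole animals and 22.0 in brain. For exon 4 the numbers were 9.35 and 9.29 in the S2 libraries, 10.6 to 11.5 in whole animals and 11.2 in brain, and for exon 6 they were 41.3 and 41.1, 43.1 to 44.4 and 43.8. Over the 8 biological libraries 18573 isoforms had a count. All 396 combinations with Ex6.11, a variant on the fixed lists, had 0 counts of 92334019, which allows a share of up to 3.25e-06%. Of the other 18612 combinations 39 had no count.

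The most abundant isoforms differed between sources. Ex4.1-Ex6.3-Ex9.6, Ex4.1-Ex6.1-Ex9.6 and Ex4.1-Ex6.6-Ex9.6 led both S2 libraries, the first with 0.650% (Clopper-Pearson interval 0.645% to 0.654%) and 0.662% (0.655% to 0.668%) of the counts. Ex4.2-Ex6.1-Ex9.30, Ex4.2-Ex6.25-Ex9.30 and Ex4.2-Ex6.42-Ex9.30 led the embryo, the first with 0.135% (0.133% to 0.137%). In L1 larva the leaders were Ex4.2-Ex6.25-Ex9.13, Ex4.2-Ex6.1-Ex9.13 and Ex4.2-Ex6.16-Ex9.13, and in L2 larva Ex4.2-Ex6.25-Ex9.13, Ex4.2-Ex6.1-Ex9.13 and Ex4.4-Ex6.25-Ex9.6. Ex4.4-Ex6.25-Ex9.6, Ex4.2-Ex6.25-Ex9.13 and Ex4.4-Ex6.16-Ex9.6 led the L3 larva, the first with 0.275% (0.272% to 0.277%). Pupa was led by Ex4.1-Ex6.6-Ex9.30, Ex4.1-Ex6.25-Ex9.30 and Ex4.1-Ex6.1-Ex9.30, and brain by Ex4.1-Ex6.25-Ex9.30, Ex4.1-Ex6.16-Ex9.30 and Ex4.1-Ex6.16-Ex9.9, with first shares of 0.0802% (0.0786% to 0.0818%) and 0.161% (0.159% to 0.163%). The most used exon 4 variant was Ex4.7 in embryo, Ex4.2 in L1 and L2 larva, Ex4.4 in L3 larva, Ex4.12 in pupa and brain and Ex4.1 in S2 cells. For exon 9 it was Ex9.30 in embryo, pupa and brain, Ex9.9 in L1 larva and Ex9.6 in L2 larva, L3 larva and S2 cells. For exon 6 it was Ex6.42 in embryo and pupa, Ex6.25 in the larvae and brain, with Ex6.1 in S2 replicate 1 and Ex6.3 in S2 replicate 2.

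Among variants in use, the S2 libraries resembled each other more closely than any other pair compared. Across the 58 variants with at least 1% of their cluster in either library, the SD of the log2 ratio of shares was 0.09, but across all 92 variants with counts in both it was 0.27, no lower than the 0.26 of L2 to L3 larva on the same 92. Between neighbouring stages it was 0.50 from embryo to L1 larva, 0.31 from L1 to L2 larva, 0.26 from L2 to L3 larva and 0.64 from L3 larva to pupa. It was 0.44 between pupa and brain and 3.54 and 3.61 between brain and the S2 libraries. Across isoforms, which are not independent replicates, log2 CPM (counts scaled to equal library totals) correlated at r = 0.956 in the S2 pair and at r = 0.535 to 0.586 between neighbouring stages. The labels do not say whether the S2 libraries came from separate cultures.

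S2 cells against whole animals asks which variants the cell line uses outside the range of the developing animal. Ex9.6 and Ex9.9 together took most exon 9 counts in S2 cells, 52.0% ± 0.0297 and 33.3% ± 0.0967 (n = 2), against 15.4% ± 5.74 and 13.4% ± 3.73 in whole animals (n = 5). Most other exon 9 variants were nearly lost. Ex4.1 stood at 24.8% ± 0.437 against 10.4% ± 0.789, and several exon 6 variants of the 5' part of their cluster were moderately higher. In edgeR's quasi-likelihood test 12 of 92 variants were higher and 40 lower in S2 cells. The calls were 1 higher and 2 lower in exon 4, 9 higher and 12 lower in exon 6, and 2 higher and 26 lower in exon 9. The log2 fold changes were 1.76 (SE 0.36, adjusted p = 0.00368) for Ex9.6, 1.32 (SE 0.28, adjusted p = 0.00484) for Ex9.9 and 1.26 (SE 0.14, adjusted p = 0.000132) for Ex4.1, each higher in both S2 libraries.

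Of the exon 9 variants, 26 of 33 were lower in S2 cells. The 12 named for the largest change were Ex9.1, Ex9.2, Ex9.3, Ex9.4, Ex9.8, Ex9.11, Ex9.14, Ex9.16, Ex9.20, Ex9.23, Ex9.26 and Ex9.29, with adjusted p from 4.83e-06 to 0.000132. Ex9.8 held 3.32% ± 2.08 of exon 9 counts in whole animals and 0.0273% ± 0.00690 in S2 cells, a 122-fold difference, and Ex9.14 held 2.16% ± 0.948 and 0.0186% ± 0.00133, a 117-fold difference. In both S2 libraries 11 exon 9 variants lay at or under the control background, so their folds are lower bounds, taken against 0.0109%. Ex9.23, at 2.35% ± 0.961 in whole animals, was at least 215-fold lower in S2 cells, Ex9.26 at least 186-fold, Ex9.20 at least 183-fold and Ex9.16 at least 149-fold. By position in the cluster, 12 of 16 proximal exon 9 variants were lower and 2 higher, and 14 of 17 distal ones were lower, with the same counts adjusted over the list alone. Both lists lay below the other variants by camera (adjusted p = 0.00564 and 0.00163, median log2 fold changes of -6.61 and -6.21, or -6.51 and -5.35 with the 4 and 7 variants at background set to their bounds). Neither call held in the other version of that test, with adjusted p = 0.428 with an estimated correlation for each list.

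The blood cell exon 9 list did not move as 1 group. It holds Ex9.6, Ex9.9, Ex9.13, Ex9.30 and Ex9.31, recalled from earlier work on S2 and blood cells that possibly includes these libraries, so it is not independent evidence of a direction. Ex9.6 and Ex9.9 were higher in S2 cells, and Ex9.30 was lower, at 0.920% ± 0.0277 against 12.9% ± 1.83 (log2 fold change -3.81, SE 0.21, adjusted p = 4.83e-06). Ex9.13 stood at 7.29% ± 0.0640 and 12.5% ± 5.55 (adjusted p = 0.188) and Ex9.31 at 1.32% ± 0.217 and 0.694% ± 0.345 (adjusted p = 0.141), and neither passed the test. The count was again 2 higher and 1 lower adjusted over the list alone, camera gave an adjusted p of 0.307, and the list's median log2 fold change of 0.93 and mean of -0.12 differed in sign. Together the list's members held 94.8% ± 0.0585 of exon 9 counts in S2 cells and 54.9% ± 15.4 in whole animals.

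The exon 6 lists were not tested against each other. Of 23 tested proximal variants of exon 6, those nearer the 5' end of the cluster, 8 were higher and 2 lower in S2 cells. Adjusted over the list alone they were 7 and 2. Camera placed the list above the other variants (adjusted p = 0.000245, or adjusted p = 0.0757 with an estimated correlation). Those other variants include the exon 9 lists, with medians of -6.61 and -6.21, so this p does not by itself show a rise in exon 6. The median log2 fold change of the proximal exon 6 list was 0.16, and 0.43 and 0.55 with the scalings of TMM and DESeq2. The 8 were Ex6.3, Ex6.5, Ex6.6, Ex6.7, Ex6.8, Ex6.9, Ex6.15 and Ex6.19, with folds from 1.23 for Ex6.15 to 1.92 for Ex6.9. Ex6.3 stood at 4.73% ± 0.0377 against 2.84% ± 0.179 (log2 fold change 0.74, SE 0.09, adjusted p = 0.000192). Of 24 distal variants 1 was higher and 10 lower, or 1 and 9 adjusted over the list alone, with a camera adjusted p of 0.588, in the upward direction against a median of -0.31. That median was -0.04 with TMM and turned to 0.07 with DESeq2, where the calls were 5 higher and 5 lower and 8 higher and 5 lower. The 1 distal variant that was higher, Ex6.47, stood at 2.16% ± 0.0144 against 0.821% ± 0.167, a 2.63-fold difference (log2 1.40, SE 0.20, adjusted p = 0.000518). In exon 4, the proximal list had 1 higher and 1 lower variant of 6 and the distal list 0 and 1 of 6, both unchanged adjusted over the list alone, with camera adjusted p of 0.307 and 0.631. Ex4.2 was 7.03-fold lower in S2 cells (1.78% ± 0.0146 against 12.5% ± 3.99, log2 fold change -2.81, SE 0.38, adjusted p = 0.000360). Ex4.8, its partner in the developmental pair, stood at 6.05% ± 0.147 and 8.56% ± 1.52 (adjusted p = 0.0579). That pair had 0 higher and 1 lower member, and 0 and 2 adjusted over the list alone, with a camera adjusted p of 0.588.

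The split of calls rested on library totals as the scale, since shares of a cluster sum to 1. TMM moved the median log2 fold change of all variants by 0.28 and gave 25 higher and 34 lower, and DESeq2 moved it by 0.39 and gave 35 higher and 34 lower, against 12 and 40. Without either S2 library only 7 variants were higher, and 8 without L2 larva. Ex6.6, Ex6.7, Ex6.8, Ex6.15 and Ex6.19 lost their calls without either S2 library (adjusted p = 0.0528 to 0.195), Ex6.7, Ex6.8, Ex6.15 and Ex6.19 without L2 larva (0.0556 to 0.0684), Ex6.8 and Ex6.15 without L1 larva (0.0664 and 0.0840), Ex6.8 and Ex6.19 without L3 larva (0.0518 and 0.0536), and Ex6.8 with limma (0.0567).

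**Figure D2:**
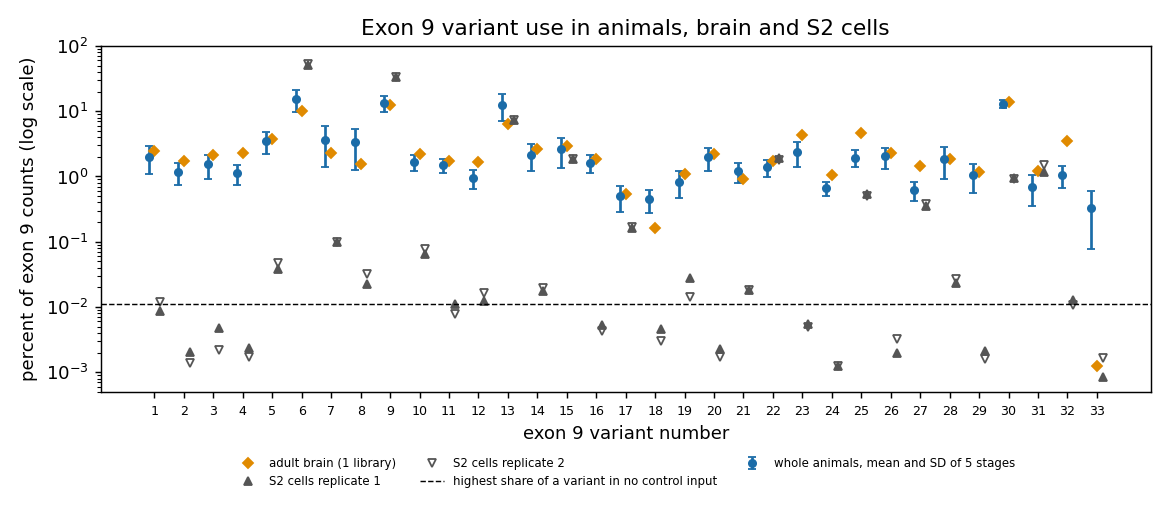
Percent of exon 9 counts (vertical, log scale) for each of the 33 exon 9 variants (horizontal) in whole animals (circles, mean and SD of 5 stages), adult brain (diamonds) and the 2 S2 libraries (triangles), with a dashed line at the control background of 0.0109%. In S2 cells Ex9.6 and Ex9.9 lie at 52.0% and 33.3%, and 11 variants lie at or under the dashed line in both libraries.

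Adult brain against S2 cells compares the organ where Dscam diversity serves neurons with the cell line. Brain used exon 9 variants that lay at background in S2 cells, except Ex9.33, which lay at background in brain too. Ex9.23 held 4.27% of exon 9 counts in brain and was at least 390-fold higher than in S2 cells, Ex9.4 held 2.31% and was at least 211-fold higher, and Ex9.20 held 2.22% and was at least 203-fold higher. In turn brain had less of Ex9.6, 10.2% against 52.0% ± 0.0297, and 2.25-fold less of Ex4.1. By edgeR's quasi-likelihood test 37 of 92 variants were higher in brain and 11 lower. The log2 fold changes were -2.35 (SE 0.63, adjusted p = 0.0154) for Ex9.6 and -1.17 (SE 0.23, adjusted p = 0.00375) for Ex4.1. The 12 named as higher were Ex9.1, Ex9.2, Ex9.3, Ex9.4, Ex9.11, Ex9.16, Ex9.20, Ex9.23, Ex9.24, Ex9.26, Ex9.29 and Ex9.32, with adjusted p from 6.75e-06 to 3.05e-05. The 11 lower ones were Ex4.1, Ex6.1, Ex6.3, Ex6.5, Ex6.6, Ex6.7, Ex6.9, Ex6.10, Ex6.47, Ex9.6 and Ex9.9.

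The fixed lists gave the same outline for brain against S2 cells. Of the exon 9 variants, 12 of 16 proximal ones were higher and 2 lower, and 13 of 17 distal ones were higher, or 14 adjusted over the list alone (camera adjusted p = 0.00153 and 0.000479, or adjusted p = 0.325 with an estimated correlation for each). Of 23 proximal exon 6 variants 1 was higher and 7 lower, and the same adjusted over the list alone (camera adjusted p = 0.000316, or adjusted p = 0.0806 with an estimated correlation). Camera again compared them with variants that include the exon 9 lists, with medians of 6.67 and 5.65, so this p does not by itself show a fall in exon 6. The median log2 fold change of the proximal exon 6 list was -0.21, and -0.64 and -0.72 with TMM and DESeq2. Of 24 distal exon 6 variants 9 were higher and 1 lower, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.383, direction down). The median of that list was 0.28, and it turned to -0.15 with TMM and -0.22 with DESeq2. In exon 4, 1 proximal variant was higher and 1 lower and 1 distal variant was higher, with the same counts adjusted over the list alone (camera adjusted p = 0.191 and 0.941). Of the blood cell list Ex9.6 and Ex9.9 were lower in brain and Ex9.30 higher, 13.8% against 0.920% ± 0.0277 (log2 fold change 3.91, SE 0.24, adjusted p = 6.75e-06). Ex9.13 and Ex9.31 did not pass (adjusted p = 0.825 and 0.920), the counts adjusted over the list alone were the same, and the list's camera adjusted p was 0.459. Ex4.2 was higher in brain, 5.54% against 1.78% ± 0.0146 (log2 fold change 1.64, SE 0.46, adjusted p = 0.0174), and Ex4.8, at 9.23% and 6.05% ± 0.147, did not pass (adjusted p = 0.0913). The pair had 1 higher member, also adjusted over the list alone, with a camera adjusted p of 0.988. TMM moved the median of all variants by -0.42 and gave 30 higher and 19 lower, and DESeq2 moved it by -0.50 and gave 30 and 30, against 37 and 11. Brain had 1 library, assumed to vary like the others. Without S2 replicate 1 only 7 variants were lower, and Ex6.7, Ex6.9, Ex6.10 and Ex9.9 lost their calls (adjusted p = 0.0510 to 0.105). The calls of Ex6.7, Ex6.9 and Ex9.9 were also lost without S2 replicate 2 (0.0579 to 0.120), of Ex9.9 without L1 larva (0.0562) and of Ex6.7 without L2 larva (0.05001).

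Adult brain against whole animals compares brain from day 1 to 3 after eclosion with whole embryos, larvae and pupae. No whole adult was sampled and the brain was female, so organ, adult age and any effect of sex cannot be told apart. Brain had more Ex9.32, 3.49% against 1.06% ± 0.386 (n = 5), and more Ex9.25, 4.59% against 1.94% ± 0.563. It had less Ex4.4, 6.70% against 12.3% ± 2.16, and less Ex6.1, 2.28% against 3.67% ± 0.506. These 4 were chosen after their values were seen, and none passed the test, each with an adjusted p of 0.187 and log2 fold changes of 1.72, 1.24, -0.88 and -0.69. By edgeR's quasi-likelihood test 0 of 92 variants passed, with 13 at an unadjusted p under 0.05, or 20 without the pupa library. DESeq2 called 1 higher and 10 lower, limma 0. On all 8 fixed lists 0 members passed, and camera's adjusted p was 0.284 or more. Adjusted over the list alone, 1 distal exon 9 variant was higher and 0 members of the other lists passed. Of the short lists brain had 10.2% Ex9.6, 12.5% Ex9.9, 6.28% Ex9.13, 13.8% Ex9.30, 1.20% Ex9.31, 5.54% Ex4.2 and 9.23% Ex4.8. Brain lay outside the range of the 5 stages for 45 of 92 variants, above it for 26 and below it for 19. That is 48.9%, where chance gives 33.3%. For exon 6 the part outside was 61.7%, for exon 9 36.4% and for exon 4 33.3%. The variant shares of 1 brain library sum to 1 within a cluster and are not independent trials, so no spread goes with the 33.3%. TMM and DESeq2 moved the median log2 fold change by -0.14 and -0.11. Without the pupa library Ex9.32 (log2 fold change 1.94) and Ex9.33 passed (adjusted p = 0.0269 for both). Ex9.33 lay under the background of 0.0109% in brain, and in whole pupa as well. In brain it was at least 38.0-fold lower than the mean of the other 4 stages, 0.416% ± 0.207. With each cluster fitted alone 7 variants passed.

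The trend over the 5 stages asks which variants change steadily through development. No steady change was found. In edgeR's quasi-likelihood test 0 of 92 variants passed, with 2 at an unadjusted p under 0.05. That number was 21 without the pupa library and 4, 0, 0 and 0 without embryo, L1, L2 and L3 larva, and none of these fits called a variant. DESeq2 called 0 as well, with 2 at an unadjusted p under 0.05, and limma called 0, with 4. On the 8 fixed lists 0 members passed, also adjusted over the list alone, and camera's adjusted p was 0.478 or more. The slopes of the blood cell list and of Ex4.2 and Ex4.8 lay between -0.21 and 0.22 on the log2 scale per stage, with adjusted p of 0.946 or more. Single steps were larger, with 1 library on each side and no test. For 3 of the steps the 3 variants with the largest log2 change among those with at least 1% of their cluster are given, a choice made after their values were seen. From embryo to L1 larva Ex9.8 went from 6.78% to 1.96%, Ex9.7 from 7.14% to 2.59% and Ex4.5 from 3.24% to 7.99%. From L3 larva to pupa Ex9.13 went from 15.6% to 5.49%, Ex9.19 from 0.527% to 1.38% and Ex9.23 from 1.18% to 3.38%. From pupa to brain Ex9.31 went from 0.435% to 1.20%, Ex9.8 from 3.75% to 1.54% and Ex9.32 from 1.65% to 3.49%. The members of the blood cell list together held 37.8% of exon 9 counts in embryo, 56.0% in L1, 69.4% in L2 and 70.7% in L3 larva, 40.7% in pupa and 44.0% in brain. The widest Clopper-Pearson interval among these was that of L1 larva, 55.9% to 56.0%.

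Independence of the exon clusters asks whether the variant in 1 cluster depends on that in another. In animals and brain the exon 4 variant of a transcript was associated with its exon 9 variant, and in S2 cells it nearly was not. The libraries are bulk. The association may thus come from pooled cells with different shares as well as from dependence within a cell, and the bits cannot tell these apart. Mutual information of exons 4 and 9 above that of independent choices averaged 0.132 bits in whole animals (0.0570 to 0.182 bits, n = 5), and was 0.0987 bits in brain and 0.00159 and 0.00201 bits in S2 cells. Pupa was the lowest of the stages and L1 larva the highest. Exons 4 and 6 shared 0.00877 ± 0.00347 bits and exons 6 and 9 shared 0.0232 ± 0.0102 bits in whole animals, against 0.00262 ± 0.000545 and 0.00278 ± 4.79e-05 bits in S2 cells (n = 2). The draws of independent choices carry read counting error only, so further scatter of isoform counts can add to small values. In S2 cells the exon 4 and 9 bits, before subtraction, were 0.984 and 0.932 of those that the exon 4 by 6 scatter predicts. Ex4.9 was nearly excluded from transcripts with Ex9.13, Ex9.6 and Ex9.30, a choice of pairs made after the values were seen. The observed over expected count averaged 0.0225 ± 0.0119, 0.0367 ± 0.0319 and 0.0423 ± 0.0234 in whole animals and was 0.0604, 0.0202 and 0.0325 in brain. Of 379 tested pairs of an exon 4 and an exon 9 variant, 101 lay below 1 and 98 above 1 in all 5 stages, which is 52.5% where chance gives 1 in 16.

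Among pairs with at least 1000 expected counts in both S2 libraries, observed over expected counts in S2 cells ranged from 0.809 to 1.27 for exons 4 and 9, from 0.590 to 1.35 for exons 4 and 6 and from 0.758 to 1.28 for exons 6 and 9. The lowest were Ex4.11 with Ex6.36 (0.590 ± 0.387, n = 2), Ex4.2 with Ex6.32 (0.626 ± 0.164), Ex4.8 with Ex6.36 (0.668 ± 0.362), Ex4.2 with Ex6.31 (0.688 ± 0.0636) and Ex4.1 with Ex6.48 (0.757 ± 0.0146). The low means of Ex6.36 rested on S2 replicate 2, with 0.864 and 0.317 with Ex4.11 and 0.924 and 0.412 with Ex4.8 in replicates 1 and 2, where Ex6.36 held 1.19% and 0.8002% of exon 6 counts. The highest were Ex4.10 with Ex6.48 (1.35 ± 0.0854), Ex4.2 with Ex6.46 (1.32 ± 0.194), Ex4.2 with Ex6.9 (1.30 ± 0.0983), Ex4.12 with Ex6.48 (1.29 ± 0.0392) and Ex6.6 with Ex9.25 (1.28 ± 0.115). Across isoforms, which are not independent replicates, log2 observed and expected counts correlated at r = 0.918 and 0.929 in S2 cells, 0.717 in brain and 0.577 to 0.767 in whole animals. Isoforms with at least 10 expected counts numbered 6368 and 5435 in S2 cells, 18042 in brain and 18048 to 18591 in whole animals. Isoform counts also scattered more about their expectation in animals and brain, so these r do not compare the dependence of clusters alone. Recombinants made up 0.380% and 0.546% of counts in the control mixtures, where exchange between copies of the same isoform is not seen, so the share in these libraries may be higher. Within the exon 9 variants that S2 cells use at 1% or more, a choice made after the values were seen, exons 4 and 9 shared 0.0525 bits in whole animals.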

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

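The set of results compared here was drawn up after the values were seen. For 46 results, variants named in the text and values per library, each whole animal library was compared with the other stages by Dixon's ratio of gap to range, which marks about 1 group in 20 by chance. It marked 2 results, 4.35% of those compared, both in the pupa library. Ex4.9 held 4.62% of exon 4 counts in pupa and 1.71% to 2.47% in the other stages. Ex9.3 held 2.61% of exon 9 counts in pupa and 1.11% to 1.46% in the other stages. No explanation was tested for either.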

How the results depend on the processing

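The alternatives were fixed before the data were examined, except the control inputs without shared variants, the pairing within S2-used exon 9 variants and the larval contrast with its scaling, which were chosen after the results were seen. No named variant that passed changed sign under any alternative run. No list that passed with camera changed direction with an estimated correlation, and the direction under fry was not recorded. Of 24 variants named for S2 cells against whole animals 19 kept their call in every setting, and of 23 named for brain against S2 cells also 19. With 7 groups and the spread from the S2 pair alone, calls came to 82, 46 and 73 for S2 cells against whole animals, brain against whole animals and brain against S2 cells, where the main counts were 52, 0 and 48. Brain against S2 cells gave 75 calls with only the libraries compared, and brain against whole animals 11 with DESeq2 and 7 with each cluster fitted alone. Leaving out 1 library at a time gave 38 to 55 calls for S2 cells against whole animals, 0 to 2 for brain against whole animals, 36 to 49 for brain against S2 cells and 0 to 0 for the trend. In such a fit a lone S2 library is assumed to vary like the other classes. Of the fixed lists 6 passed with camera, 0 with an estimated correlation and 11 with fry.

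Control counts outside the inputs, 0.512% and 0.732%, were 0.655% and 0.935% with inputs that share no variant, 0.587% and 0.789% with 7 inputs, 0.480% and 0.684% with 9, and 0.403% and 0.629% for isoforms with at least 10 counts. The SD of log2 ratios in the S2 pair, 0.0930, was 0.0891 over variants of at least 0.1% and 0.269 over all variants. S2 isoforms detected, as 47.9% of the whole animal mean, were 51.9% without thinning, 40.2%, 38.5% and 37.8% at minimums of 2, 5 and 10 counts, 36.3% above the control background, and 46.9% to 48.9% with 1 library left out. The effective number in S2 cells, 19.0% of that in whole animals, ranged from 17.6% to 21.3% with 1 library left out and stayed within 18.9% to 19.0% otherwise. The bits shared by exons 4 and 9 in whole animals, 0.132, were 0.0525 within the exon 9 variants used in S2 cells and 0.119 to 0.151 with 1 stage left out. The cause of these shifts was not tested, beyond the fewer variants, counts or libraries that a setting keeps. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The limit of 3 counts was 4.98e-05% or less of an S2 library, below the control background of 0.0109% for exon 9 variants.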

Other observations

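All tests in this part were chosen after the results they examine were seen. Larvae were compared with embryo and pupa pooled as 1 group, and not with each of them alone. The adjusted p below do not account for the choice of this split. By edgeR's quasi-likelihood test 5 variants were higher in the 3 larval libraries than in embryo and pupa, Ex9.31, Ex9.13, Ex4.5, Ex9.9 and Ex6.25, and 12 were lower, Ex4.10, Ex4.11, Ex9.1, Ex9.7, Ex9.8, Ex9.15, Ex9.16, Ex9.19, Ex9.20, Ex9.22, Ex9.28 and Ex9.29. Ex9.13 held 16.4% ± 2.19 of exon 9 counts in larvae and 6.79% ± 1.83 in embryo and pupa (log2 fold change 1.27, SE 0.25, adjusted p = 0.0203), and Ex4.5 held 8.52% ± 0.975 and 3.91% ± 0.956 of exon 4 counts (log2 fold change 1.12, SE 0.21, adjusted p = 0.0177). Ex9.28 held 1.19% ± 0.179 in larvae and 2.90% ± 0.317 in embryo and pupa (log2 fold change -1.29, SE 0.16, adjusted p = 0.00911). Of the 10 splits of the 5 stages into 3 and 2, 1 gave as many as 17 calls, the real one, and the highest other gave 3. These splits are too few for a share under 0.05, so they cannot decide whether larvae differ from embryo and pupa beyond chance. Of the 12 lower variants 10 were exon 9 variants outside the blood cell list, whose members together held more of exon 9 in larvae. With these variants scaled to their own total, 0 of the 10 passed, as their median log2 fold change went from -1.09 to -0.25, and 4 calls were left, Ex9.13, Ex4.5 and Ex6.25 higher and Ex4.10 lower. Ex9.9, Ex9.31 and Ex4.11, which were not rescaled, also lost their calls at unchanged log2 fold changes of 0.75 (SE 0.19 before and 0.21 after), 1.38 (SE 0.38 and 0.36) and -0.79 (SE 0.19 in both), with adjusted p from 0.0348, 0.0479 and 0.0295 to 0.0725, 0.0629 and 0.05004. The root mean square log2 change of variants outside the list, as a share of exon 9 and as a share of the rest, was 1.09 and 0.24 from L3 larva to pupa and 0.56 and 0.21 from L1 to L2 larva, but 0.74 and 0.62 from embryo to L1 larva, 0.29 and 0.28 from L2 to L3 larva and 0.56 and 0.55 from pupa to brain.

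Ex9.33, the last variant of its cluster, was a larval and embryonic variant in these libraries. It held 0.161% (Wilson interval 0.159% to 0.164%) of exon 9 counts in embryo, 0.669% (0.662% to 0.676%) in L1, 0.419% (0.416% to 0.423%) in L2 and 0.414% (0.411% to 0.418%) in L3 larva. In pupa it held 0.00605% (0.00562% to 0.00651%), in adult brain 0.00125% (0.00109% to 0.00145%) and in S2 cells 0.000837% and 0.00166%, all under the control background of 0.0109%. Ex4.9, which held 2.66% ± 1.14 of exon 4 counts in whole animals, held 0.0244% ± 0.00347 in S2 cells, where the control background was 0.0225%.

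The first pattern is the pairing of exon 4 with exon 9. Few sampled molecules are argued against. The bits in animals and brain were at least 13.2 times those that the scatter of exons 4 and 6 predicts. The low use of most exon 9 variants in S2 cells is argued against too as the reason for their low bits. Within the variants S2 cells use, the bits in animals and brain were at least 31.9 times the S2 mean. Uneven use of those variants in S2 cells was not taken into account. Nor was their low use of Ex4.9 and Ex4.2, 0.0244% and 1.78% against 2.66% and 12.5% in whole animals. In animals and brain the pairing lay mostly between the blood cell exon 9 list and the other exon 9 variants. Ex4.9 was left out here, since its exclusion had been seen. That split then carried 73.5% to 87.5% of the bits in the 6 animal and brain libraries. Of 1000 splits of exon 9 within 2 percentage points of the list's share of counts, 0 reached the list in any of them. The highest matched split carried 69.3%, in brain. In S2 cells 93 and 252 matched splits reached the list. Every transcript carries 1 exon 9 variant, so the split locates the pairing. It cannot tell whether a mixture of 2 kinds of molecules from different cells explains it. Ex4.9 made up 0.0980% to 0.335% of the counts with a list variant and 3.76% to 7.56% of the others, and Ex4.2 made up 21.7% and 4.84% in L2 larva but 5.60% and 5.50% in brain. The list may mark blood cells or another tissue, and since no cell type was sampled apart from brain and S2 cells, whether the molecules come from different cells stays untested.

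The second pattern is the low counts of variants that a library should lack. Wrong assignment of reads from similar variants as the whole source is argued against for exons 6 and 9, because the shares of variants of no input followed those in animals and brain in both mixtures, at r = 0.875 or more across 39 exon 6 variants and at r = 0.762 (95% interval 0.524 to 0.889) or more across 25 exon 9 variants. It stays open for exon 4, with 4 variants (r = 0.7098, -0.791 to 0.993), and as part of the source, since between the mixtures, whose dominant inputs differ, r was 0.902 for exon 6 but 0.545 for exon 9. Carry-over from the animal and brain libraries as the whole source is argued against, since Ex4.9 made up 1.48% (95% interval over drawn isoforms 1.14% to 1.88%) of the S2 counts of exon 9 variants at background, or 1.80% (1.35% to 2.32%) and 0.674% (0.281% to 1.16%) in the single libraries, against 4.196% to 7.64% in animals and brain. Carry-over as part of the source remains a possible explanation, with that share at least 31.01 times the 0.0262% and 0.0217% of other S2 counts. The ratio does not single out carry-over, because rare S2 transcripts paired as in animals could give it too. In animals and brain Ex4.9 was 11.8- to 54.5-fold more frequent with exon 9 variants outside the blood cell list than with its members.

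The third pattern is the scatter of isoform counts about the product of their variants' shares. The number of reads is argued against, since in every biological library the variance was at least 52.3 times that of independent reads in the exon 4 by 6 table, and at least 25.9 times in the exon 6 by 9 and 3 cluster tables. For combinations regulated alike across stages the test cannot decide. Departures from the pairwise expectation correlated across isoforms at r = 0.0379 at most over 15 pairs of animal and brain libraries. Even the S2 pair reached only r = 0.156, so scatter within a library could hide combinations shared by the stages. Few sampled molecules remain a candidate source in animals and brain. There the variance ratios of the exon 4 by 6, exon 6 by 9 and 3 cluster tables differed at most 1.59-fold within a library. By the exon 4 by 6 table the reads could stand for 26034 molecules in L1 larva, the lowest, to 77674 in brain, the highest. Of isoforms with at least 100 expected counts, 0.566% in brain to 6.19% in L3 larva had 0 counts, and 3.79% in brain to 21.6% in L3 larva had up to 10. The percent that so few molecules would give was not computed, so these values do not decide for or against them. In the exon 4 by 9 table, left out for its pairing, the variance ratio was 2384 to 9826 in the animal and brain libraries. In S2 cells the 3 tables differed 1.67- and 2.02-fold, the second past the factor of 2 that was set. Few sampled molecules thus stay open as a source in S2 cells.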
